A study of Mus musculus with 4 samples.

How the data were processed

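Total RNA from fibroblasts of WT and Zip13KO mice had been hybridised by the authors to Affymetrix Mouse Gene 2.0 ST arrays, per the labels, as 2 biological replicates per group. The deposited values are intensity on a linear scale. Affymetrix Expression Console and RMA, which corrects background, normalizes between arrays and summarises probes, are named in the submitters' processing notes without versions. The annotation and summary level are not given in the sources used here. RMA returns log2 values, and these ran from 21.8 to 10826, so they appear to have been raised to a linear scale before deposit. The tests had been planned for log2 values, and log2 of the deposited intensity was therefore taken first, with no pseudocount. Normalization between arrays makes their overall distributions alike, so a change shared by most genes would not be seen. Summaries of a whole transcript also compress the differences of dim genes and cannot separate near-identical genes.

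Gene names came from the platform annotation given with the table. Of 41345 rows, 23521 had 1 gene symbol, 1814 had several and 16010 were without a gene name here. Of the rows with 1 symbol, 23328 matched the RefSeq gene table of assembly GRCm38.p6 by gene ID, and the match changed 0 symbols. That table served only for names, gene types and the order of neighbouring genes. Where a gene had more than 1 row, as 1082 did, the row with the highest mean over the 4 arrays was kept, which left 22180 genes. No intensity filter was applied.

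Arrays were grouped by the genotype in their labels. Each gene was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend in intensity, two-sided), with Benjamini-Hochberg adjustment over genes and a threshold of adjusted p under 0.05. Differences are Zip13KO minus WT in log2 units, with the standard error of the moderated fit. The fit had 2 residual and 15.1 prior degrees of freedom. Gene lists were tested with camera at a preset correlation of 0.01 between genes, over the 40 of 41 lists with at least 5 measured genes, adjusted over those lists. Camera with an estimated correlation, camera on ranks and fry were run as well. The first of these refers its statistic to the 2 residual degrees of freedom, so a list can lose its call whatever its correlation. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

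The groups, the design, the lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule names Slc39a13; the 12 genes per direction with the largest difference among those past the threshold, without overlap between groups and above the median of all rows in the higher group; and up to 4 members per list past the threshold, or else the member with the smallest p. It leaves predicted-gene, RIKEN, microRNA and small RNA names out of the top genes and only counts them. These were recognised at first by patterns in the symbol alone, which found 198 among the genes past the threshold. That pass put AF357355 among the 12 genes that fell most, at -2.83 (adjusted p = 2.60e-09), with an SD of 0.65 in WT. The gene table lists it as a small nucleolar RNA, so gene types were added to the patterns, which took the count to 202 and brought in Epb41l4a. This correction was made after the values were seen, including that AF357355 did not pass in the robust fit (adjusted p = 0.0872) while Epb41l4a did (4.66e-16).

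Alternatives were the replicate number as a block, a filter that kept rows above the array median on at least 2 arrays, a further quantile normalization, arrays centred on their median, eBayes without trend and with robust variance, the mean of a gene's rows, a fit and adjustment over all rows, and each array left out in turn. With 1 array left in a group, it is assumed to vary like the other group. Crossed replicate numbers and centring on blocks of 50 neighbouring genes were added after the data had been seen, as were a fit over all rows adjusted over genes and a fit over genes adjusted over all rows.

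The pipeline was tested on simulated data drawn from the means of the 22180 genes, with 50 genes changed at each of 4 sizes. It recovered 98% of genes changed by 0.5 log2 units and 100% of those changed by 1, 2 and -1, with 13 false calls among 212. A shifted list was found at adjusted p = 1.24e-40 and 0 of 39 unchanged lists were called. The simulated genes were drawn independently of each other, so this result does not cover lists of correlated genes. The estimated correlation of the real cell cycle list was 0.437. An earlier version of the simulation drew each gene's spread from its raw SD over 2 arrays, and recovery was poor. Raw SDs overstate how much spreads differ between genes. The raw SD was replaced by the moderated SD, which is pulled towards the trend over genes. Moderated SDs differ less between genes than the fit allows for. These rates therefore hold for such evened spreads and may be too favourable for real data.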

Results

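Gene expression was measured in mouse fibroblasts on 4 Affymetrix Mouse Gene 2.0 ST arrays, a single-colour design with 1 array per RNA sample. The arrays formed a wild-type group (WT) and a group labelled Zip13KO, with 2 biological replicates each. Zip13 is the protein of Slc39a13, a member of the ZIP family of zinc transporters. The table held 41345 rows, and the median intensity per array lay between 94.5 and 96.1. Arrays of the same group resembled each other most: Pearson's r over all rows was 0.994 within WT and 0.994 within Zip13KO, against 0.983 to 0.985 between groups. The difference between the 2 arrays of a group had an SD over genes of 0.118 log2 units in WT and 0.125 in Zip13KO. The number of arrays limits the precision, and the labels do not say whether replicates came from separate animals or cultures. The p-values of genes therefore rest on the spread between these samples, which may be technical in part. Those of lists in camera at the preset correlation compare a list with the other genes. They are judged by the spread between genes, not between arrays.

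The comparison between groups asks how gene expression differs where the zinc transporter is altered, with zinc balance in and around the Golgi as the study's stated interest. Slc39a13 itself did not differ. Its log2 intensity was 8.89 ± 0.07 in WT and 8.94 ± 0.07 on the arrays labelled Zip13KO (SD, n = 2 each), a difference of 0.04 (95% interval -0.12 to 0.20, limma adjusted p = 0.820). The gene had 1 row in the table, and the positions of its probes relative to the altered part of the gene are not known, so this value does not check the labels. Directions below follow the labels as given. Without WT replicate 2 the difference was -0.00410, and without Zip13KO replicate 2 it was -0.00554, neither past the threshold.

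Some metal-responsive genes rose on the arrays labelled Zip13KO, and few zinc transporters passed the test. Of the 9 measured genes of the metallothionein and metal-response list, 4 rose and 1 fell, and adjusted over the list alone 5 rose and 1 fell. Slc39a10, a zinc importer at the cell surface, rose by 0.55 log2 units (SE 0.08). Mt2, a metallothionein that binds zinc, rose by 0.43, Hmox1, which encodes a haem oxygenase, rose by 0.30, and Mtf1, the zinc-sensing transcription factor, fell by 0.29. The list was past the threshold in the upward direction (camera adjusted p = 0.00578; adjusted p = 0.481 with an estimated correlation), though not by fry (adjusted p = 0.106). Of the 13 other ZIP importers, Slc39a10 rose and Slc39a7, which releases zinc from the secretory pathway, fell by 0.38, with the same 1 and 1 adjusted over the list alone (list adjusted p = 0.816). Among 8 measured ZnT exporters none passed in limma, over all genes or adjusted over the list alone, although 3 had an unadjusted p under 0.05 (list adjusted p = 0.495). The closest was Slc30a6 at -0.19 (adjusted p = 0.0669), and it passed after a filter on low values (adjusted p = 0.0445) and after centring on chromosome blocks (0.0261). Mtf1 did not pass without WT replicate 1 (adjusted p = 0.0519), nor after centring on chromosome blocks, where its difference was -0.17 (adjusted p = 0.132).

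Many genes differed between the groups, most of them by a small amount. Of 22180 genes tested, 3786 were past the threshold, with 1552 higher and 2234 lower on the arrays labelled Zip13KO. Of these, 72.6% differed by less than 0.5 log2 units, and 259 differed at least 2-fold (95 higher and 164 lower). The arrays of one group lay entirely above those of the other for 51.5% of all genes, where chance gives 33.3%. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333, so calls rest on the moderated model. The call total dropped to 1806 when every row of the table entered the fit and the adjustment. Of the genes that the naming rule gave and that passed in the main fit, 18 did not pass then (adjusted p from 0.0528 to 0.310): Mt2, Hmox1, Mtf1, Sec61b, Nemp1, Kdm1b, Kdm4c, Nsd3, Kat2a, Sod3, Xist, Pkp1, Ovol1, Cd68, Cd14, Csf1r, Erbb3 and Egr2. Genes named only under Other observations were not followed through the alternatives.

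Samd5 rose from 6.62 ± 0.01 to 9.77 ± 0.01 (SD, n = 2 each), which is 8.87-fold (adjusted p = 4.13e-15). Adcyap1r1, the receptor of the neuropeptide PACAP, rose by 3.14 log2 units (SE 0.09), within the error of Samd5 at 3.15 (SE 0.08), Dlk1, an imprinted Notch-related ligand, 8.03-fold, and Msln, the surface protein mesothelin, by 2.97. Cdh3, which encodes P-cadherin, rose by 2.91, the receptor phosphatase Ptprq by 2.52 and Crabp1, a retinoic acid binding protein, by 2.50. The list of 12 was completed by Bhlhb9 (2.36), Lgals3bp (2.35), the cation exchanger Slc24a3 (2.28), the carbonic anhydrase Car12 (2.26) and the cytokine Il33 (2.21). Myl9, a regulatory light chain of myosin, fell most, from 11.93 ± 0.00 to 7.95 ± 0.04 (SD, n = 2 each), which is 15.8-fold lower (adjusted p = 6.71e-17). Plac8 fell by 3.89 (SE 0.08), within the error of Myl9 at -3.99 (SE 0.07). The matrix protein periostin (Postn, -3.68), Igfbp7 (-3.41), the small heat shock protein Hspb8 (-3.30) and Nrn1 (-3.19) fell as well. Arsj fell by 2.82 and Actg2, a smooth muscle actin, fell by 2.81. Papss2, which makes the sulfate donor for glycosaminoglycans, fell by 2.75, and lower values were also found for thrombomodulin (Thbd, -2.68), the gelatinase Mmp2 (-2.68) and Epb41l4a (-2.53). The mean of their rows put Arsj at -1.56 and Lgals3bp at 1.59, so their places among these genes depend on the row chosen. Actin genes are near-identical in sequence, so Actg2 and Acta2 may share signal on the array and their separate values are uncertain.

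**Figure D1:**
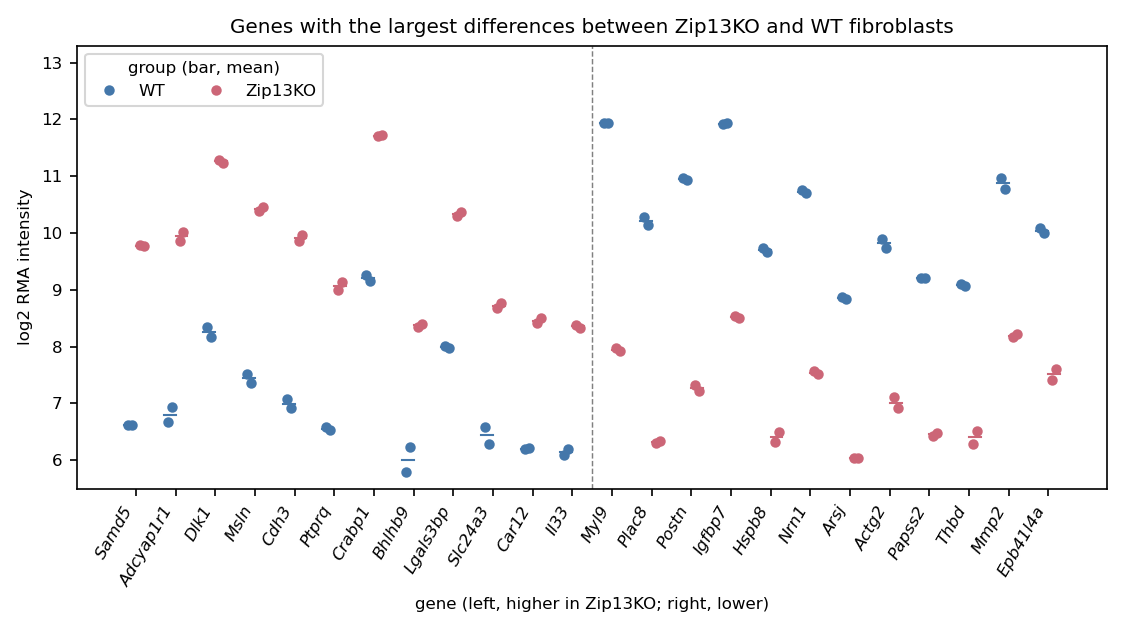
Log2 RMA intensity of each array for the 12 genes that rose most and the 12 that fell most. Blue points are WT arrays, red points arrays labelled Zip13KO and bars group means; Samd5 stood at 6.62 and 9.77, and Myl9 at 11.93 and 7.95.

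Among genes of the Golgi and of transport between the endoplasmic reticulum and the Golgi, more fell than rose on the arrays labelled Zip13KO. Many did not pass, and calls leaned lower among all genes too. Of 22180 genes, 2234 fell and 1552 rose, and of 13819 kept by a filter on low values, 2351 fell and 1627 rose. In the Golgi stress list, 15 of 34 genes fell and 3 rose, and adjusted over the list alone 16 fell and 3 rose. Creb3l1, a membrane-bound transcription factor of secretory cells, fell by 1.70 log2 units (SE 0.08). It is among the 50 genes nearest to Slc39a13 on chromosome 2, and whether this place bears on its fall was not tested. Kdelr3, a receptor that returns proteins to the endoplasmic reticulum, fell by 0.86 and the sialyltransferase St3gal1 fell by 0.73, while Uap1l1 rose by 0.61. The list was past the threshold (camera adjusted p = 1.41e-04; adjusted p = 0.439 with an estimated correlation). Of 53 genes of the COPI and COPII coats and their tethers, 22 fell and 4 rose, and adjusted over the list alone 23 fell and 5 rose. Sec23a and Sec24d, components of the COPII coat, fell (-0.92 and -0.46), as did the COPI subunit Copz2 (-0.73) and the tether subunit Trappc6b (-0.46). The list was past the threshold (camera adjusted p = 3.07e-04; adjusted p = 0.757 with an estimated correlation), though not by fry (adjusted p = 0.171). Among 32 golgins and stacking proteins, 8 fell and 1 rose, and adjusted over the list alone 10 fell and 1 rose. Golga2, Golga4, Golgb1 and Acbd3 belong to the Golgi stress list too. The stress and coat lists share Arf4 and Sec16a, so these lists are not independent of each other. Golga2, the golgin GM130, fell by 0.53, as did Golim4 (-0.50) and Acbd3 (-0.37), while Cux1, whose locus also encodes a nuclear transcription factor, rose by 0.73 (0.38 as the mean of its rows). The golgin list was past the threshold (adjusted p = 0.0279; adjusted p = 0.908 with an estimated correlation). It did not pass without WT replicate 1 (adjusted p = 0.156), without Zip13KO replicate 1 (0.309), after a filter on low values (0.124), after a further quantile normalization (0.0702) or by fry (0.263).

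**Figure D2:**
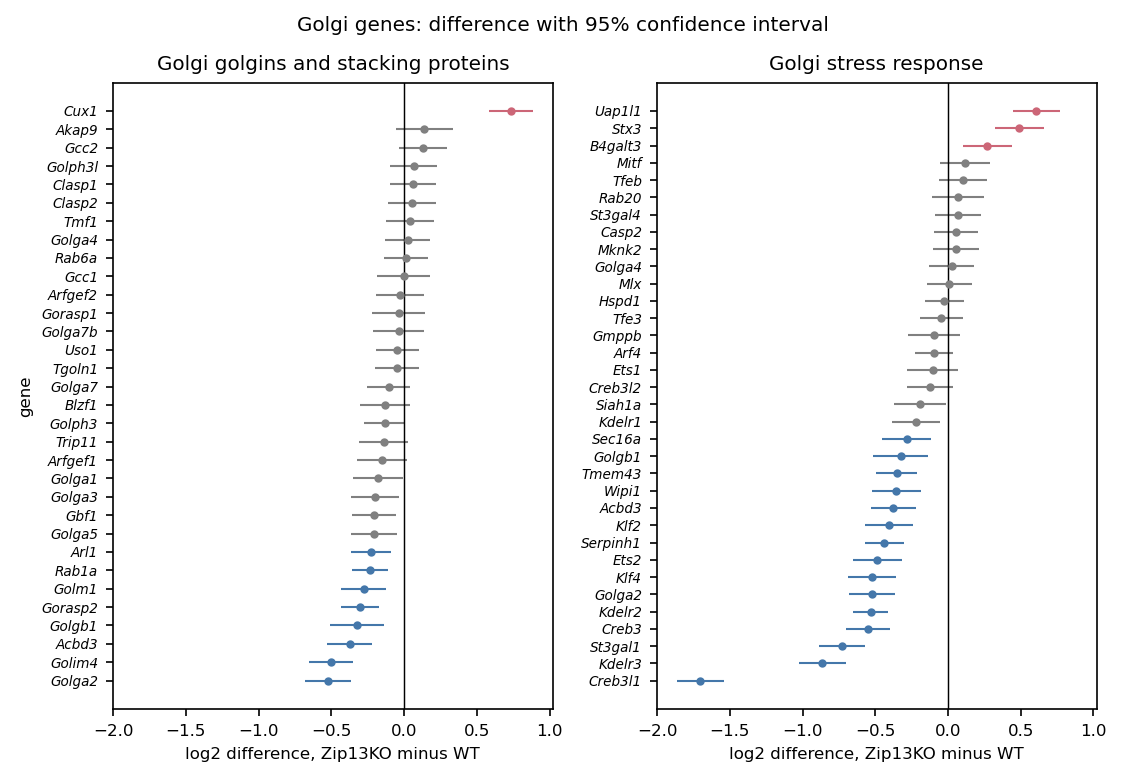
Log2 difference (Zip13KO minus WT) of each measured gene of the golgin list (left) and of the Golgi stress list (right), with 95% confidence intervals as bars. Red points rose, blue points fell and grey points did not pass; 8 of 32 golgin genes and 15 of 34 stress genes fell, with Creb3l1 lowest at -1.70.

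Enzymes that build sugar chains in the Golgi changed in both directions. Of 57 Golgi glycosyltransferases, 7 rose and 11 fell, and adjusted over the list alone 8 rose and 13 fell (list adjusted p = 0.287). St3gal5, which makes the ganglioside GM3, fell by 0.96 log2 units, as did B3galt1 (-0.80) and St3gal1 (-0.73), while Gcnt4 rose by 0.71. Of 44 proteoglycan and glycosaminoglycan synthesis genes, 14 fell and 2 rose, and adjusted over the list alone 16 fell and 3 rose (list adjusted p = 2.27e-04; adjusted p = 0.481 with an estimated correlation). Besides Papss2, the hyaluronan synthase Has2 (-1.61), the chondroitin sulfotransferase Chst11 (-1.61) and the heparan sulfotransferase Hs6st2 (-0.78) fell. In the unfolded protein response list, 13 of 38 genes fell and 3 rose, and adjusted over the list alone 16 fell and 4 rose (list adjusted p = 0.00623; adjusted p = 0.691 with an estimated correlation). The chaperone Dnajb11 (-0.71), the stress sensor Atf6 (-0.50) and the translocon subunit Sec61b (-0.45) fell, whereas Chac1, a glutathione-degrading enzyme, rose by 1.20. The list did not pass without WT replicate 1 (adjusted p = 0.0517), after a filter on low values (0.0537) or by fry (0.116), and Sec61b did not pass without WT replicate 2 (-0.27, adjusted p = 0.0992) or after centring on chromosome blocks (-0.19, adjusted p = 0.269). The mean of its rows was -0.28.

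In each extracellular matrix list more genes fell than rose, with a majority lower only among those that modify and crosslink collagen. Of 28 collagen modification genes, 19 fell and 2 rose, and adjusted over the list alone 19 fell and 3 rose (list adjusted p = 2.35e-10; adjusted p = 0.430 with an estimated correlation). The protease Tll1, which processes procollagen, fell by 2.13 log2 units (SE 0.08), as did lysyl oxidase (Lox, -1.36), the lysyl hydroxylase Plod2 (-1.16) and Pcolce2 (-1.14). Of 43 collagens, 12 fell and none rose in limma, none with an unadjusted p under 0.05 in that direction, and adjusted over the list alone 13 fell. The basement membrane chains Col4a1 (-1.56) and Col4a2 (-1.38) fell, as did Col12a1 (-1.46) and Col6a3 (-0.97). The list was past the threshold (camera adjusted p = 9.88e-05; adjusted p = 0.481 with an estimated correlation). Of 42 elastic fibre and matricellular genes, 17 fell and 7 rose, and adjusted over the list alone 18 fell and 8 rose (list adjusted p = 2.09e-04; adjusted p = 0.678 with an estimated correlation). Besides Postn, the thrombospondins Thbs1 (-2.51) and Thbs2 (-2.06) fell, as did Ltbp2 (-1.58). Matrix proteases and their inhibitors followed, with 15 of 41 lower and 2 higher, over all genes and adjusted over the list alone (list adjusted p = 1.46e-04; adjusted p = 0.439 with an estimated correlation). The list did not pass on ranks (adjusted p = 0.0558). Adamts5, which cleaves aggrecan, fell by 2.27, as did Adam12 (-1.42) and the inhibitor Timp3 (-1.10), beside Mmp2.

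More contractile and TGF-beta responsive genes fell than rose in the same arrays. Of 24 myofibroblast and smooth muscle markers, 14 fell and none rose in limma, and adjusted over the list alone 15 fell and 1 rose (list adjusted p = 1.06e-11; adjusted p = 0.439 with an estimated correlation). Besides Myl9 and Actg2, smooth muscle actin (Acta2) fell by 2.08 log2 units and transgelin (Tagln) fell by 1.49. The matrix lists above moved in the arrays in which markers of contractile cells moved too. Of 30 TGF-beta responsive genes, 17 fell and 7 rose, and adjusted over the list alone 18 fell and 7 rose, led by Postn, Acta2, Ltbp2 and Tagln (list adjusted p = 1.05e-08; adjusted p = 0.315 with an estimated correlation). Some of these 30 genes are matrix genes or contractile markers as well. BMP responsive genes did not pass as a list (adjusted p = 0.195), with 4 of 34 higher and 8 lower, or 5 higher and 10 lower adjusted over the list alone. Fst and Grem1, secreted antagonists of TGF-beta family ligands, rose by 1.88 and 1.42, and Smoc2 and the inhibitory Smad7 fell (-0.80 and -0.69).

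Many interferon-stimulated genes rose on the arrays labelled Zip13KO. Of 47 measured, 23 rose and none fell in limma, with none lower at an unadjusted p under 0.05, and adjusted over the list alone 26 rose. Bst2, which tethers budding viruses, rose by 1.88 log2 units (SE 0.08), Oasl2 by 1.49, Ifit1 by 1.40 and Rtp4 by 1.33 (list adjusted p = 4.32e-15; adjusted p = 0.315 with an estimated correlation). NF-kB and inflammatory genes went both ways, with 7 of 36 higher and 10 lower, or 9 higher and 11 lower adjusted over the list alone (list adjusted p = 0.585). Besides Il33, the chemokine Ccl5 rose by 0.94, while Ccl7 and the prostaglandin synthase Ptgs2 fell (-1.34 and -1.26).

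Many p53 targets fell and several cell cycle genes rose. Of 28 p53 targets, 17 fell and 1 rose, and adjusted over the list alone 20 fell and 2 rose (list adjusted p = 1.05e-08; adjusted p = 0.315 with an estimated correlation). The cell cycle inhibitor Cdkn1a (p21) fell by 1.60 log2 units, as did Ccng1 (-1.07), Eda2r (-0.68) and Epha2 (-0.58). Of 64 cell cycle genes, 14 rose and 5 fell, and adjusted over the list alone 14 rose and 8 fell. Cdk6 and Ccnd1, partners at entry into the cycle, rose by 1.06 and 0.96, the phosphatase Cdc25b by 0.55 and Ccnb2 by 0.42 (list adjusted p = 0.0323; adjusted p = 0.940 with an estimated correlation). This list did not pass without WT replicate 2 (adjusted p = 0.154), without Zip13KO replicate 2 (0.474), after a filter on low values (0.0537), on ranks (0.0621), after centring on chromosome blocks (0.215) or by fry (0.480). Of 43 senescence and secretory genes, 14 fell and 5 rose, and adjusted over the list alone 15 fell and 6 rose (list adjusted p = 0.0322; adjusted p = 0.481 with an estimated correlation). Igfbp7, Cdkn1a and Ccl7 were among those that fell, and Igfbp5 rose by 1.62. The senescence list did not pass after a filter on low values (adjusted p = 0.0625) or on ranks (0.307).

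The lists of lipid synthesis and of immediate early genes were past the threshold downward, whereas those of NRF2 targets, glycolysis and lysosome genes were not past it in camera. Of 31 cholesterol and fatty acid genes, 14 fell and 1 rose, and adjusted over the list alone 16 fell and 2 rose (list adjusted p = 6.73e-05; adjusted p = 0.684 with an estimated correlation), though not by fry (adjusted p = 0.0901). Hmgcs1 and Hsd17b7, enzymes of cholesterol synthesis, fell (-0.96 and -0.51 log2 units). Mylip, which degrades the LDL receptor, and the cholesterol exporter Abca1 fell (-0.57 and -0.53), and Abca1 was at -0.27 after centring on chromosome blocks. Of 34 immediate early and serum response genes, 16 fell and 8 rose, and adjusted over the list alone 18 fell and 10 rose (list adjusted p = 0.0312; adjusted p = 0.684 with an estimated correlation). The phosphatase Dusp1 fell by 2.16, as did Ccn2 (-1.10), Ccn1 (-0.97) and Ier3 (-0.87). The mean of its rows put Ccn2 at -0.62. This list did not pass after a filter on low values (adjusted p = 0.137), a further quantile normalization (0.0588), on ranks (0.0900), after centring on chromosome blocks (0.0509) or by fry (0.0540). NRF2 targets had 4 of 35 higher and 8 lower, or 6 higher and 9 lower adjusted over the list alone (list adjusted p = 0.359), with Cbr1 at -0.83, Sod3 at -0.64, Nqo1 at -0.60 and Gpx8 at -0.59. In fry, which tests whether a list moves one way on balance, NRF2 targets passed downward (adjusted p = 0.0370). Glycolysis and hypoxia genes had 8 of 30 higher and 8 lower, the same adjusted over the list alone (list adjusted p = 0.816). Adm and Ddit4 fell (-1.95 and -0.61), and Egln3 and Eno2 rose by 1.45 and 0.55. Lysosome and autophagy genes had 7 of 45 higher and 9 lower, or 7 higher and 10 lower adjusted over the list alone (list adjusted p = 0.869). Gpnmb and Ctsb rose by 1.66 and 0.52, and Atp6v1a and Ctsk fell (-0.74 and -0.68), and Atp6v1a was at -0.46 after centring on chromosome blocks.

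Some chromatin and nuclear envelope genes passed the test in each direction, and none of these lists did. Histone acetylation enzymes and readers had 8 of 33 higher and 1 lower, or 9 higher and 6 lower adjusted over the list alone (list adjusted p = 0.303). The deacetylase Hdac5 rose by 0.57 log2 units, the coactivator Ncoa3 by 0.49, Kat6b by 0.36 and Kat2a by 0.32. Histone methylation enzymes had 5 of 47 higher and 5 lower, or 6 higher and 7 lower adjusted over the list alone (list adjusted p = 0.645), with Smyd3 at 0.38, Kdm1b at 0.37, Kdm4c at -0.33 and Nsd3 at -0.32. DNA methylation genes had 2 of 20 higher and 3 lower, the same adjusted over the list alone (list adjusted p = 0.816). Gadd45g, Zbtb38 and Gadd45b fell (-1.15, -1.10 and -0.45), and Ahcy rose by 0.86. Nuclear envelope genes had 2 of 45 higher and 6 lower, the same adjusted over the list alone (list adjusted p = 0.568), with the linker protein Sun2 at -0.44, the prelamin protease Zmpste24 at -0.41, Nup93 at -0.37 and Nemp1 at 0.38. Leaving out a single array ended the calls of Kat2a (without WT replicate 2, adjusted p = 0.156), Kdm1b (without Zip13KO replicate 2, 0.0552), Kdm4c (without WT replicate 2, 0.0507, and without Zip13KO replicate 2, 0.0606) and Nsd3 (without WT replicate 1, 0.123). Without WT replicate 2 Kat2a was at 0.21. Centring on chromosome blocks ended those of Kdm4c (-0.14, adjusted p = 0.299) and Nsd3 (-0.18, adjusted p = 0.129) and put Kat6b at 0.24. The mean over a gene's rows ended that of Nemp1 (0.18, adjusted p = 0.131) and put Ahcy at 0.29 and Sun2 at -0.27.

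Fibroblast and positional genes changed in both directions. Of 22 fibroblast identity genes, 7 rose and 7 fell, the same adjusted over the list alone (list adjusted p = 0.869). Cd34 and Pdgfra rose by 1.73 and 1.04 log2 units, and Fbln2 and Pdgfrb fell (-1.41 and -0.92). Of 36 Hox genes, which mark position along the body, 11 rose and 9 fell, or 11 rose and 12 fell adjusted over the list alone (list adjusted p = 0.816). Hoxc9 and Hoxa9 rose by 1.16 and 1.13, and Hoxb5 and Hoxa2 fell (-1.32 and -1.08). Wnt pathway genes had 7 of 48 higher and 6 lower, the same adjusted over the list alone (list adjusted p = 0.869), with Sfrp1 at -1.25, Rspo2 at 0.69, Dkk2 at -0.65 and Lrp5 at 0.56.

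Few markers of other cell types passed, apart from the contractile list above. Adipocyte markers had 3 of 25 higher and 3 lower, the same adjusted over the list alone (list adjusted p = 0.922), with Lpl at 0.92, Plin2 at -0.72, Pparg at -0.39 and Agpat2 at 0.38, and the mean of its rows put Lpl at 0.53. Among 23 bone and cartilage markers 1 rose, Sox9 by 0.35 (list adjusted p = 0.816), and among 27 skeletal muscle markers 1 rose, Pax3 by 1.42 (list adjusted p = 0.536), each also adjusted over the list alone. Of 23 endothelial markers none passed in limma, over all genes or adjusted over the list alone, while 1 had an unadjusted p under 0.05 (list adjusted p = 0.869). Cdh5 was closest at 0.20, and it passed after centring on chromosome blocks (adjusted p = 0.00772). Epithelial markers had 1 of 25 higher and 1 lower, the same adjusted over the list alone (list adjusted p = 0.922), with Pkp1 at -0.77 and Ovol1 at 0.31, and Pkp1 did not pass in the robust fit (adjusted p = 0.202). Pkp1 was at -0.46 without WT replicate 1, and Ovol1 did not pass after centring on chromosome blocks (0.20, adjusted p = 0.106). Melanocyte and Schwann cell markers had 1 of 18 higher and 2 lower, the same adjusted over the list alone (list adjusted p = 0.869), with Pmp22 at -1.36, Erbb3 at 0.50 and Egr2 at -0.28. Macrophage and leukocyte markers had 1 of 31 higher and 2 lower, or 0 and 1 adjusted over the list alone (list adjusted p = 0.922), with Cd68 at 0.40, Cd14 at -0.32 and Csf1r at -0.26. Calls ended without WT replicate 2 for Cd68 (0.13, adjusted p = 0.562, against 0.66 without WT replicate 1), without Zip13KO replicate 2 for Cd14 (0.0917), and without either WT replicate 1 or Zip13KO replicate 2 for Csf1r (0.212 and 0.255) and Egr2 (0.169 and 0.0783). Centring on chromosome blocks ended those of Cd68 (adjusted p = 0.0641) and Csf1r (0.124), and the robust fit that of Cd68 (0.159). The sex-linked list had 4 measured genes, under the minimum of 5 for a list test. Xist, expressed from the inactive X chromosome, was above 9 log2 units on all 4 arrays and rose by 0.49, though not without WT replicate 2 (0.22, adjusted p = 0.126, against 0.76 without WT replicate 1) or in the robust fit (adjusted p = 0.239), and adjusted over the list alone it was the only call.

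**Figure D3:**
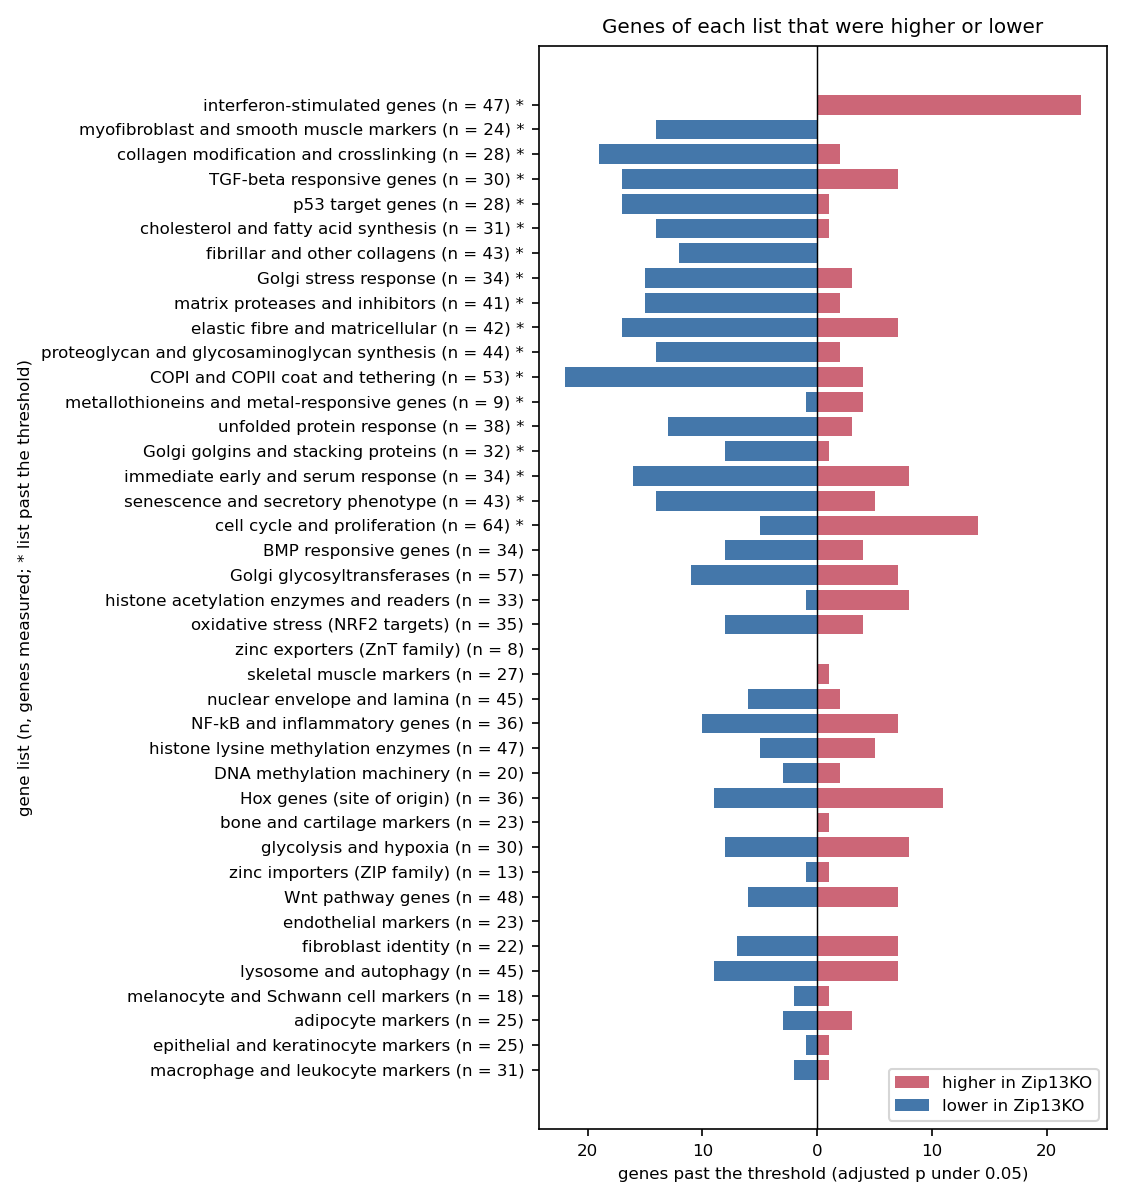
Number of genes past the threshold in each of the 40 tested lists, with genes that rose to the right (red) and genes that fell to the left (blue). Asterisks mark the 18 lists past the threshold, of which interferon-stimulated genes had 23 genes higher and none lower.

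Of the 40 lists tested, 18 were past the threshold by camera with a preset correlation, 3 upward and 15 downward. With an estimated correlation none passed, and 4 had an unadjusted p under 0.05, while fry called 12. The estimated correlation was 0.00108 for interferon-stimulated genes and -0.00355 for p53 targets. It was 0.00577 for TGF-beta responsive genes and -0.0182 for the senescence list. All of these lie under the preset 0.01. Correlation between genes therefore does not explain why these lists were lost. For the other lists past the threshold, correlation cannot be told apart from the 2 degrees of freedom used there. In each of the 18 the median difference had the sign of the test. Median, mean and test differed in sign for ZIP importers, DNA methylation, glycolysis, Wnt, Hox, fibroblast identity, skeletal muscle and endothelial lists, none of which passed.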

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

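The tests of chance, gene length, copy number, swapped arrays, probe position and other splits were chosen after the results were seen, as was the test of chromosome blocks on Hox genes.

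Some rows left out of the gene test passed too. Among 16010 rows without a gene name here, 476 were past the threshold when all rows were tested (312 higher and 164 lower), which is 2.97% of them, a smaller share than the 2448 of all 41345 rows. Among 1814 rows with several gene names, 110 were past it (69 higher and 41 lower).

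Differences came in blocks along chromosomes. On chromosome 16, 193 of 397 genes above the table median fell and 10 rose (median -0.22). Of those 397 genes, 80.9% lay below 0, called or not. On chromosome 4, 290 fell and 27 rose, whereas on chromosome 14, 128 rose and 21 fell. All block medians were negative on chromosomes 16 (-0.34 to -0.10) and 4 (-0.39 to -0.05). They were all positive on chromosome 14 (0.04 to 0.12), while chromosome 2 held both signs (-0.09 to 0.12). Along chromosome 2, blocks 1 to 11 were negative and blocks 12 to 20 positive. The SD of the medians of blocks of 50 neighbouring genes was 0.0819, against at most 0.0335 in 10000 random gene orders and 0.0338 in orders matched on gene length and brightness (permutation p = 1e-04 for each, the smallest these orders can give), which argues against chance order and against length or brightness. A difference in chromosome copy number between the cultures may contribute: among chromosome 16 genes not past the threshold, 62.61% and 70.89% on its left and right sides lay below 0, against 50.4% elsewhere. These shares leave out the called genes and no DNA was measured, so copy number and an effect of genotype cannot be told apart here.

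Slc39a13 did not differ on the arrays labelled Zip13KO. A swap of 1 array between the groups is argued against, since the lowest correlation within a group exceeded the highest between groups by 0.00819. A probe set outside the altered part of the gene could leave the signal at its WT level, and the difference of 0.0421 for its only row cannot tell this from labels that are wrong for a whole group. Of its 50 nearest genes on chromosome 2, 10% were past the threshold, against 17.1% of all genes, and the largest difference among them was that of Creb3l1, which fell by 1.70.

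The 3 ways of splitting the 4 arrays into pairs are too few to give a share under 0.05. The real split, which was 1 of 3 to reach its own count, gave 3786 genes and the highest of the others gave 0. Each of the other splits mixes 1 WT with 1 Zip13KO array, so the difference between the groups widens the spread within its pairs. Few calls were bound to follow there, and the counts do not serve as a null.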

How the results depend on the processing

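Counts of genes stayed within 1.5 times the reported 3786 under the normalization, filter, variance and row-averaging alternatives (3607 to 4161, the low end from centring on chromosome blocks, chosen after seeing the data) and between 2921 and 3808 when an array was left out. The exception was a fit and adjustment over all rows, which gave 1806, all among the 3786. Taken apart after seeing the data, the fit over all rows gave 2124 when adjusted over genes, with prior degrees of freedom of 4.08 against 15.1, and the fit over genes gave 3428 when adjusted over all rows, so most of the drop came with the fit. Genes with at least a 2-fold change numbered 245 to 272 under the alternatives run. Slc39a13 ranged from -0.00554 to 0.0898 when an array was left out and was never past the threshold. Gene lists past the threshold numbered 18 and fell to 0 in camera with an estimated correlation, while other alternatives gave 12 to 18. That camera setting also cuts the degrees of freedom to 2, so its 0 does not measure correlation alone. With the replicate number as a block 3364 genes passed, 3271 of them shared, and 15 lists, without golgins, the unfolded protein response and the cell cycle (adjusted p = 0.271, 0.183 and 0.0876); deviations of same-numbered arrays correlated at -0.12, so the numbers do not show a pairing. Crossed numbers as a block, chosen after seeing the data, gave 5208 genes. Centring on chromosome blocks brought the share of higher genes from 41.0% to 50.5%, with 2835 genes shared and 41 changes of sign. Of 152 named genes, 18 no longer passed with all rows tested, 7 after centring on blocks (2 others then passed), 3 in the robust fit, 1 with rows averaged, and 4, 5, 0 and 5 without WT replicate 1, WT replicate 2, Zip13KO replicate 1 and Zip13KO replicate 2. Where not stated above, the cause was not tested. Signal over background is not known for these summaries, which limits what dim genes can show.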

Other observations

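All values and sets here were chosen after the data were seen, apart from the Hox list. All 10 measured mitochondrially encoded genes rose, by 0.21 to 0.47 log2 units (median 0.30), among them ND6 by 0.47, COX3 by 0.46 and CYTB by 0.21. Of 8 class I histocompatibility genes, 3 rose: H2-K1 by 2.06 (SE 0.08), H2-Q4 by 0.76 and H2-T23 by 0.52. These genes are similar in sequence and vary between mouse strains, so their separate values are uncertain.

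Imprinted genes changed in both directions. Of 16 measured, Dlk1, Peg3 and Ndn rose (8.03-fold for Dlk1, and by 0.72 and 0.51 log2 units for the others). The 5 that fell were Rian (-1.08), Plagl1 (-0.53), Igf2 (-0.48), Cdkn1c (-0.42) and Grb10 (-0.27). Dlk1 and Rian belong to the same imprinted cluster, and Meg3, also of that cluster, did not pass (adjusted p = 0.998).

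Of 16 Hox genes numbered 6 or less, 9 fell and 1 rose, and of 15 numbered 9 or more, 9 rose and 0 fell. Across the 36 genes, which are not independent replicates, Spearman's rank correlation between number and difference was 0.613 (permutation p = 0.00013) and Pearson's r was 0.574 (permutation p = 3e-04), which argues against a chance order. The rank correlation was 0.80 in HoxA, 0.65 in HoxB and 0.75 in HoxC, but 0.02 in HoxD, so the relation is not one of every cluster. Over all clusters it was 0.636 after centring on chromosome blocks. Genes of 1 Hox cluster are neighbours and are centred by much the same value, so centring could hardly change the relation within a cluster. It therefore cannot decide whether a regional effect contributes. A candidate explanation is that the cultures came from different body sites, which the labels do not give, so for these 36 genes site of origin and genotype cannot be told apart.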
